A study of Mus musculus with 12 samples.

How the data were processed

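The series holds liver RNA sequencing of 12 mice, 6 controls and 6 given selenium-enriched Aspergillus oryzae A02, and each mouse is 1 library. The replicate numbers come from the sample titles and name mice. Per the labels' protocols, RNA was isolated from frozen tissue with TRIzol and cleaned on an RNeasy column, and libraries followed standard Illumina procedures. Whether polyadenylated RNA was selected or rRNA depleted, and whether counting used strand, is not given in the sources used here. Per the submitters' processing notes, HISAT2 2.1.0, RSEM 1.2.8 and DESeq2 were used with the GRCm39 build.

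The authors deposited expression as TPM, per gene and library, with gene identifiers and symbols in the series table. TPM divides by transcript length and scales each library to a fixed total, so a large rise in a few abundant genes lowers the values of all others, and neither depth nor counting error can be had from it. The TPM values of the deposited series table equalled those of the deposited single-library tables in 100% of cases. The deposited series table also gives a log2 fold change of control over selenium by the authors, whose sign was turned here to selenium minus control. Its p-value columns, raw and adjusted, are likewise the authors' own, as deposited. No count test was run, since counts were not used here.

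Values were analysed in R 4.3.3 with limma 3.58.1, and plots were drawn with matplotlib 3.10.9. Genes with a TPM of at least 1 in 6 or more of the 12 libraries were kept, which left 9980. They were tested on log2(TPM + 1) with limma's linear model and empirical Bayes with an intensity trend, two-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale, with its pseudocount of 1, understates the change of genes with low values. Log2 changes are selenium minus control throughout, and intervals are 95% intervals of the moderated estimate. Tested on simulated data with the means and spreads of the 9980 genes and 200 changed genes, the procedure recovered 44.8% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 97.6% of those changed 3-fold, with 4.51% false calls. Each gene was drawn independently in this simulation, so these rates do not cover variation that genes share between mice.

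Before the data were examined, 59 gene lists were written from general knowledge, covering selenium biology, liver metabolism, stress responses, the clock, sex bias and markers of liver and other cell types. Of their 1368 entries, 1367 matched a symbol in the files, and the 49 lists with 5 or more measured members were tested with limma's camera at a preset correlation of 0.01. camera with an estimated correlation, fry, which asks whether a list moves on balance in 1 direction, and an exact permutation test of the per-library mean over all 924 labellings served as alternatives. Shares of the total TPM were compared with the same exact permutation test, two-sided. Genes of a list can vary together between mice more than the preset correlation allows, so the number of lists called in other splits of the libraries was also counted.

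The named genes followed a rule fixed in advance. It took the 12 genes in each direction with the largest log2 change among those past the threshold with at least 5 TPM in a group and a proper symbol. Where fewer than 5 passed in a direction, it took the 8 with the smallest p instead. It added the 4 members with the smallest p of each list past camera and of the 6 lists with the smallest camera p, and a fixed set of selenoprotein, metabolic and clock genes. G6pc1 stands in the files under its older symbol G6pc. One gene of the fixed set is not reported here. Genes outside the rule, named after their values were seen, are Nfkbia, Akr1d1, Hjv, Gm14760, Hspa5, Selenos, Selenom, Gpx3, Nr1d1, Cry1, mt-Rnr1 and mt-Rnr2, and those among the additional observations.

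Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-of-ratios scaling, quantile normalization, TPM rescaled without mitochondrial-encoded genes, limma without the trend, robust empirical Bayes, array weights, an exact permutation test per gene, a block for the replicate number, leaving out each library, a minimum of 2-fold and an unadjusted p. The alternatives chosen after seeing the data were the first principal component of the clock gene list as a covariate, its first 2 components as covariates, a loess correction of each library for transcript GC content, only the 8 libraries with Dbp under 10 TPM, and, for the share of major urinary protein genes, leaving out each library and TPM rescaled without mitochondrial-encoded genes. Leaving out each library was likewise added for the genes named after their values were seen, and the clock components and the GC correction for the further list of nuclear RNAs. The reference available was GENCODE release M21, on another build than the authors' files, so no coordinates are given. It supplied only GC content and biotype by gene identifier, for 98.6% of the tested genes.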

Results

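Liver RNA was profiled by RNA sequencing in 12 male C57BL/6J mice, 6 controls and 6 given Aspergillus oryzae A02 grown with selenium. A. oryzae is a filamentous food fungus, and the labels give the dose as 0.5 mg selenium per kg by gavage each day, on a normal diet. The mice were 6 weeks old at the start, and the protocol speaks of 10 mice in a group, of which 6 libraries per group were analysed here. The design text gives 8 weeks of feeding, while the sample descriptions say 14 weeks, and whether the latter is an age is not stated. The tissue label is liver and a further label names hepatocytes, so the values are read here as whole liver. Each library was a table of TPM values for 57010 genes, a measure of transcript abundance corrected for length and scaled to the same total in every library, so the sequencing depth behind each value is unknown. Of these genes, 9980 reached 1 TPM in at least 6 libraries and were tested. Pairwise correlations of log2 values between libraries ran from 0.935 to 0.986, so no library was a copy of another.

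The comparison of selenium with control asks how liver gene expression differed in mice given the selenium-enriched fungus. Fungus and selenium were given together, so their effects cannot be told apart here. The word selenium names this group below, not the element as the cause. The clearest differences were lower transcripts in the selenium group. Srsf5, a serine and arginine-rich splicing factor, fell from 101 ± 15.9 TPM in controls to 44.5 ± 6.27 TPM (mean ± SD, n = 6 per group). Malat1, a long noncoding RNA that stays in the nucleus, fell from 37.1 ± 16.5 to 8.39 ± 2.38 TPM. Clk1 and Clk4, kinases that phosphorylate splicing factors of the Srsf family, fell from 29.0 ± 6.44 to 13.1 ± 2.51 TPM and from 16.1 ± 3.25 to 8.44 ± 1.78 TPM. In Srsf5, Malat1, Clk1 and Clk4 the highest selenium library lay below the lowest control library.

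Other genes with lower transcripts came from several functions. Rsrp1, which encodes an arginine and serine-rich protein, fell from 89.7 ± 26.3 to 40.1 ± 7.63 TPM, and Pnisr, which encodes a serine and arginine-rich protein of nuclear speckles, fell from 9.08 ± 2.95 to 3.62 ± 0.988 TPM. Tcim, a small regulator of transcription, fell with a log2 change of -1.55, as did the arrestin-domain gene Arrdc2 (-1.30), the interferon-related developmental regulator Ifrd1 (-1.08), Ankrd16 (-0.92) and Fam193b (-0.90). The mitochondrial-encoded mt-Atp6, a subunit of ATP synthase, fell from 5524 ± 919 to 3252 ± 411 TPM. Outside the naming rule, and singled out after their values were seen, Nfkbia, the inhibitor of NF-kappaB, fell from 24.4 ± 2.86 to 14.3 ± 2.75 TPM, and the bile acid synthesis gene Akr1d1 and the hepcidin regulator Hjv fell with log2 changes of -0.71 and -0.67.

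Fewer transcripts were higher. Mavs, the mitochondrial adaptor of antiviral RNA sensing, rose from 8.48 ± 2.47 to 16.1 ± 2.48 TPM, with every selenium library above every control. The only other gene past the threshold in this direction, Gm14760, carries a prediction name and averaged 0.672 TPM in controls and 2.93 TPM with selenium; it was named after its value was seen. The next genes by p under the naming rule did not pass. They were Sel1l3, Mup2, Trappc4, Zbtb7b, Sult5a1, Dnajb9 and Inhbe, with log2 changes of 0.63, 0.77, 0.82, 0.63, 1.08, 0.85 and 0.73 and adjusted p from 0.0671 to 0.0721. Mup2 belongs to the major urinary proteins, a family of near-identical genes whose reads cannot be assigned with certainty.

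In limma with an intensity trend on log2(TPM + 1), two-sided, 33 genes passed a Benjamini-Hochberg adjusted p of 0.05, 2 higher and 31 lower in selenium, and 9 of them had a clone or prediction name or no symbol. The adjusted p was 0.00331 for Srsf5 (log2 change -1.17, SE 0.13), 0.0113 for Malat1 (-1.94, SE 0.27), 0.0113 for Clk1 (-1.09, SE 0.16) and 0.0440 for Mavs (0.88, SE 0.17). In 30 of the 33, which were picked for low p in the same libraries, the groups did not overlap. The same held for 163 tested genes, or 1.63%, where chance gives 0.216% per gene. Genes can vary together between mice, so that difference in shares is no test. At an unadjusted p under 0.05 there were 700 higher and 1142 lower genes. Most calls lay near the threshold. The count was 22 without control 3 and 31 without selenium 6, and leaving out another library gave 7 (control 2), 8 (selenium 2 or 5), 10 (control 5, selenium 1 or 4), 13 (selenium 3), 15 (control 4), 19 (control 1) or 171 (control 6). Srsf5, Malat1, Clk1 and Ifrd1 passed in each of these 12 fits, Mavs in 1, and the other named genes past the threshold in 3 to 6. Quantile normalization gave 2 higher and 10 lower genes, and an exact permutation test per gene called 0, its smallest adjusted p being 0.133.

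**Figure D1:**
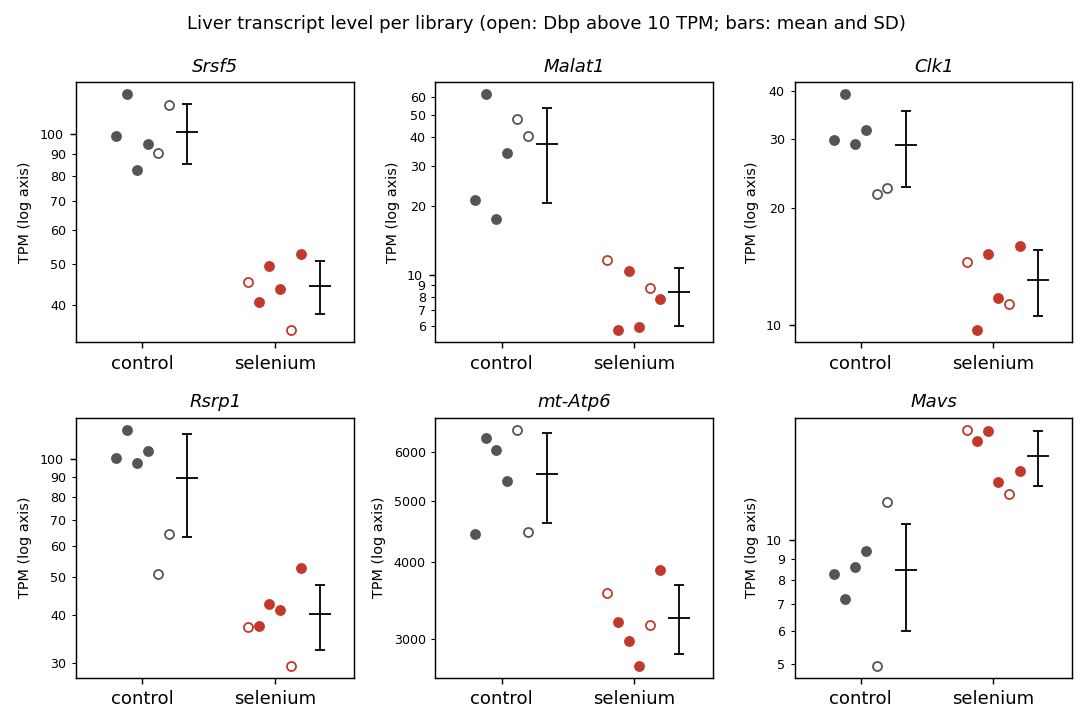
Transcript level (TPM, logarithmic axis) of 6 genes in the 6 control and 6 selenium libraries, each point 1 library, open points being the libraries with Dbp above 10 TPM, with the group mean and SD beside them. Srsf5 lay between 82.5 and 124 TPM in controls and between 35.0 and 52.6 TPM with selenium, and Mavs between 4.94 and 12.4 and between 12.98 and 18.65 TPM.

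The libraries differed in the clock gene Dbp in a way the groups do not explain. Dbp, a transcription factor with a strong daily rhythm in liver, stood at 15.7 and 28.5 TPM in controls 5 and 6 and at 31.5 and 53.6 TPM in selenium 1 and 5, against 0.720 to 1.44 TPM in the other 8 libraries. Nr1d1, a repressor in the clock, was at 1.04 to 2.92 TPM in controls 1 to 4, at 21.9 and 27.1 TPM in controls 5 and 6, and at 8.60 to 29.3 TPM with selenium. The labels give no time of sampling. The difference between the group means of Dbp did not pass (exact permutation p = 0.561, n = 6 per group), and the clock gene Per1 was at 2.39 ± 1.37 and 1.95 ± 1.05 TPM. By limma Nr1d1 and the clock gene Cry1, named after their values were seen, had log2 changes of 1.57 and -0.62, with unadjusted p = 0.0300 and 0.0172 and adjusted p = 0.220 and 0.184, and that of Cry1 was -0.39 without control 4. The second principal component of the 16 clock genes differed between the groups (exact permutation p = 0.0368, n = 6 per group). The log2 change of Srsf5 was -1.08 among the 8 libraries with low Dbp and -1.35 among the 4 with high Dbp, that of Malat1 was -1.90 and -2.01, and that of Mavs 0.87 and 0.89. Tested alone, an alternative chosen after seeing the data, the 8 libraries with low Dbp gave 34 higher and 13 lower genes, 9 of them among the 33. These 8 libraries were not matched for clock state, as their first clock component ran from -0.28 to -0.23 in controls and from -0.16 to -0.11 with selenium. With the first 2 clock components as covariates, likewise chosen after seeing the data, 0 genes passed in limma. The median log2 change of the 31 lower genes was -0.81 and all 31 had an unadjusted p under 0.05. These 31 were picked for low p in the same libraries, so this does not show that the difference withstands the covariates.

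Selenoproteins, which carry selenium as selenocysteine, were the genes closest to the treatment, and none of the 19 measured passed the test. Gpx1, the main cytosolic glutathione peroxidase, averaged 2008 ± 350 TPM in controls and 2034 ± 422 TPM with selenium, a log2 change of 0.01 with a 95% interval of -0.34 to 0.36. Selenop, the plasma selenium carrier made by liver, stood at 1884 ± 471 and 1936 ± 340 TPM, a change of 0.05 with an interval of -0.32 to 0.43. The intervals for Gpx4 (-0.65 to 0.13), Selenow (-0.40 to 0.39), Selenoh (-0.24 to 0.54), Sephs2 (-0.38 to 0.24) and Dio1 (-1.72 to 1.14) also included 0. Txnrd1, the cytosolic thioredoxin reductase, was at 19.3 ± 3.26 and 27.7 ± 6.86 TPM, and Msrb1, a methionine sulfoxide reductase, at 243 ± 36.7 and 319 ± 49.0 TPM. By limma their log2 changes of 0.48 and 0.39 had unadjusted p = 0.0136 and 0.0125 and adjusted p = 0.168 and 0.163. Selenos (0.27) was also positive and Selenom (-0.44) negative at an unadjusted p under 0.05, both named after their values were seen.

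As a list, the selenoproteins had a median log2 change of 0.01 and a mean of -0.04, with 10 of 19 positive. limma's camera, a test of a list against the other genes, called their direction up with an adjusted p of 0.647, and 0 passed when adjusted over the list alone. Selenon, Gpx2, Dio2, Dio3 and Selenov stayed below the filter. The 15 measured genes of selenocysteine synthesis and selenium handling had a median of 0.04, with 2 lower adjusted over the list alone, 0 over all genes and a camera adjusted p of 0.951. Non-selenium antioxidant enzymes (median 0.02, 22 genes, adjusted p = 0.811) and targets of the oxidative stress regulator NRF2 (-0.03, 24 genes, adjusted p = 0.972) did not pass either, and the NRF2 target Nqo1 was at 3.68 ± 1.39 and 2.80 ± 1.11 TPM.

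**Figure D2:**
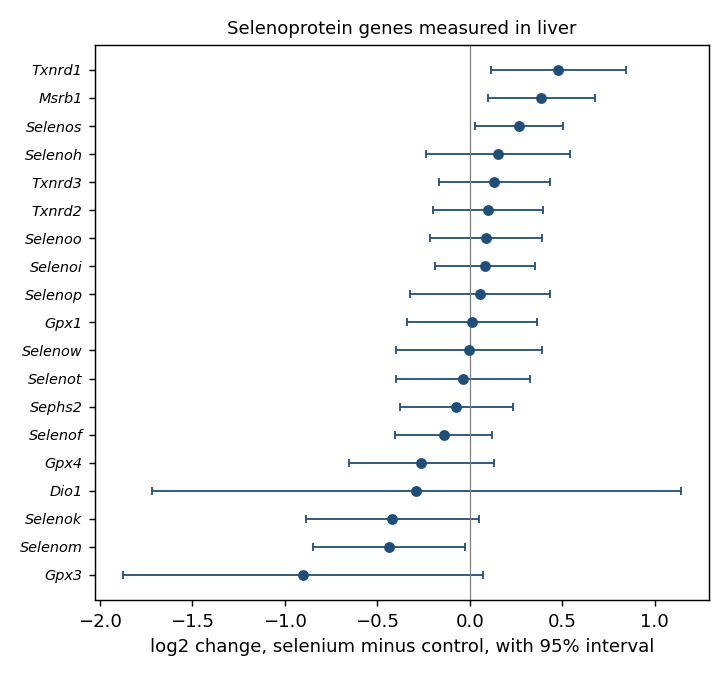
The log2 change (selenium minus control) of the 19 selenoprotein genes measured, with the 95% interval of limma, ordered by size. Gpx1 and Selenop lay at 0.01 and 0.05, Txnrd1 at 0.48 and Gpx3 at -0.90 with an interval of -1.87 to 0.07. Gpx3 was at 26.0 TPM in control 6, without which its change was -0.46.

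Among 49 gene lists tested, genes of endoplasmic reticulum stress leaned higher with selenium. All 23 members had a positive log2 change, with a median of 0.52. Control 4 had the highest list mean of the controls, at 0.13 relative to the mean of all libraries, against -0.60 to -0.09 in the others and 0.09 to 0.47 with selenium. Hspa5, the main chaperone of the endoplasmic reticulum, named after its values were seen, averaged 204 ± 71.1 TPM in controls and 322 ± 52.4 TPM with selenium, and the chaperone Hyou1 14.6 ± 7.33 and 34.2 ± 11.6 TPM. Derl3, a factor of protein degradation from the endoplasmic reticulum, and the co-chaperones Dnajb9 and Dnajb11 had log2 changes of 0.81, 0.85 and 0.52. Of the 23, 11 were higher adjusted over the list alone and 0 over all genes, with 13 at an unadjusted p under 0.05 in limma. The list passed camera with a preset correlation (adjusted p = 4.03e-11) and was lost with an estimated one (adjusted p = 0.986 with an estimated correlation). In all, camera with the preset correlation called 5 lists in the real comparison and 4 to 24 in 99 other splits of the libraries. Its per-library mean differed by 0.52 (exact permutation p = 0.00866, n = 6 per group, adjusted p = 0.212), by 0.63 in the 8 libraries with low Dbp (exact p = 0.0857) and by 0.31 in the 4 with high Dbp. The median was 0.29 with the first 2 clock components as covariates.

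The mRNAs encoded by the mitochondrial genome leaned lower with selenium. All 13 had a negative log2 change, with a median of -0.60, which was -0.35 after a correction for GC content chosen after seeing the data (camera adjusted p = 0.00321). mt-Cytb, a subunit of respiratory complex III, averaged 11363 ± 2312 TPM in controls and 7254 ± 1415 TPM with selenium, and mt-Nd3, of complex I, 5104 ± 1067 and 3325 ± 383 TPM. For mt-Nd6, transcribed from the opposite strand to the other mRNAs, the change was -0.82, and strand use in counting is not given in the sources used here. Of the 13, 12 were lower adjusted over the list alone and 1, mt-Atp6, over all genes. The list passed camera (adjusted p = 7.87e-08) and was lost with an estimated correlation (adjusted p = 0.986 with an estimated correlation). The share of all TPM held by mitochondrial-encoded genes fell from 17.3 ± 3.43% to 11.6 ± 1.97% (exact permutation p = 0.00433, n = 6 per group). The mitochondrial rRNAs mt-Rnr1 and mt-Rnr2 had log2 changes of 0.19 and 0.02 (limma adjusted p = 0.546 and 0.959). The mean of the 13 mRNAs differed by -0.56 in the 8 libraries with low Dbp (exact p = 0.0571) and by -0.62 in the 4 with high Dbp. The 72 nuclear-encoded respiratory chain genes had a median of -0.09 (camera adjusted p = 0.245).

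Heat shock genes and targets of PPAR-alpha, the fatty acid sensor that drives fat oxidation, leaned higher. In the heat shock list 17 of 20 log2 changes were positive, with a median of 0.30, and 4 genes were higher adjusted over the list alone against 0 over all genes. Control 4 stood apart, with a list mean of 0.42 relative to the mean of all libraries, against -0.43 to -0.16 in the other controls and -0.03 to 0.59 with selenium. The chaperone Hsph1 was at 13.9 ± 8.07 and 28.4 ± 10.7 TPM, the co-chaperone Bag3 at 5.88 ± 1.29 and 14.8 ± 9.30 TPM, and Dnajb1 at 5.87 ± 1.57 and 10.5 ± 4.38 TPM. Hspa1b, whose reads are shared with the near-identical Hspa1a, was at 6.67 ± 2.92 and 25.4 ± 25.9 TPM, with 77.7 TPM in selenium 3. In the fat oxidation list 29 of 34 changes were positive, with a median of 0.28 and 0 genes past adjusted over the list alone or over all genes, and 10 at an unadjusted p under 0.05 in limma. Control 4 had the highest mean of all libraries on this list, 0.49, against -0.58 to 0.11 in the other controls and -0.18 to 0.40 with selenium. Hadha, of mitochondrial beta-oxidation, was at 53.9 ± 17.8 and 85.0 ± 14.2 TPM, Cpt1a, which admits fatty acids to mitochondria, at 50.6 ± 10.7 and 74.7 ± 20.9 TPM, and the lipid droplet gene Plin2 at 204 ± 51.4 and 331 ± 84.2 TPM. Ppara itself and Creb3l3 had log2 changes of 0.96 and 0.39. Camera's adjusted p was 8.72e-05 for heat shock and 1.77e-06 for fat oxidation, and both were lost with an estimated correlation (adjusted p = 0.986 with an estimated correlation). For the per-library means the exact permutation p was 0.0411 for heat shock and 0.165 for fat oxidation (n = 6 per group, adjusted p = 0.504 and 0.867). In the 8 libraries with low Dbp the medians were 0.23 and 0.28, with camera adjusted p of 0.143 and 0.00576, and with the first 2 clock components as covariates they were 0.17 and 0.13.

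Immediate early genes, which respond within minutes to stimuli, leaned lower, with 16 of 19 log2 changes negative and a median of -0.36. Dusp1, a phosphatase of MAP kinases, was at 11.3 ± 5.66 TPM in controls and 4.13 ± 1.47 TPM with selenium, Gadd45g at 19.5 ± 12.5 and 5.07 ± 3.21 TPM, Zfp36, which promotes decay of cytokine mRNAs, at 18.2 ± 6.02 and 9.76 ± 3.17 TPM, and Myc at 1.90 ± 0.407 and 1.03 ± 0.467 TPM. Of the 19, 4 were lower adjusted over the list alone and 0 over all genes, with 6 at an unadjusted p under 0.05 in limma. The list passed camera (adjusted p = 0.00132) and was lost with an estimated correlation (adjusted p = 0.986 with an estimated correlation). Its 2 lowest libraries were selenium 1 and 5, which also had high Dbp. Controls 5 and 6 had high Dbp too, but their list means of 0.25 and 0.29 lay within the range of the other controls. The list mean differed by -0.97 in the 4 libraries with high Dbp. In the 8 with low Dbp it differed by -0.22 (exact permutation p = 0.229). Selenium 3 had the highest list mean, at 0.42 relative to the mean of all libraries, against 0.03 to 0.31 in controls. In the 8 libraries with low Dbp the median was -0.08 (camera adjusted p = 0.0835). It was -0.50 with the first 2 clock components as covariates (camera adjusted p = 2.45e-05), -0.71 with a pseudocount of 0.1 and -0.56 to -0.29 with 1 library left out, where all 12 fits passed camera.

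**Figure D3:**
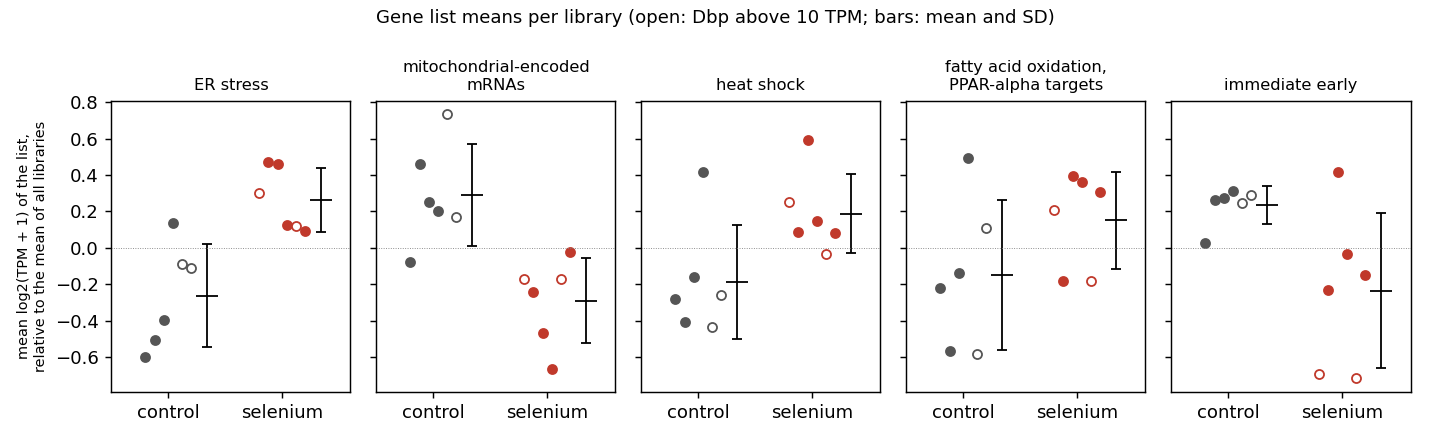
Mean log2(TPM + 1) of 5 gene lists per library, relative to the mean of all libraries, for 6 control and 6 selenium libraries, open points being those with Dbp above 10 TPM, with the group mean and SD beside them. The means for endoplasmic reticulum stress were -0.26 in controls and 0.26 with selenium, and those for mitochondrial-encoded mRNAs 0.29 and -0.29.

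Male-biased liver genes came next and lay at the threshold, with a median of 0.16 and a camera adjusted p of 0.0506. The list passed in 6 of the 12 fits that left out a library, those without control 1, 2 or 3 or selenium 3, 4 or 6, and without a filter (adjusted p = 0.00113), with TPM rescaled without mitochondrial genes (0.0159) and with the first 2 clock components as covariates (1.60e-06). Its median ran from 0.02 with array weights to 0.34 with these components. It did not pass with array weights (adjusted p = 0.938), in the 8 libraries with low Dbp (adjusted p = 0.933) or with an estimated correlation (adjusted p = 0.986 with an estimated correlation). Serpina1e, one of several near-identical protease inhibitor genes, had a log2 change of 0.97, Susd4 0.50, Ugt2b38 0.95 (0.61 without control 5) and C8a -0.28, and 1 of the 22 members, higher, passed adjusted over the list alone. The major urinary protein genes together held 24.1 ± 6.82% of TPM in controls and 33.0 ± 5.07% with selenium (exact permutation p = 0.0303, n = 6 per group). With 1 library left out, a check added after the data were seen, this difference passed in 8 of 12 fits, with an exact p of 0.0519 to 0.0584 in the other 4, those without control 5 or selenium 1, 3 or 5, and with TPM rescaled without mitochondrial genes it did not pass (exact permutation p = 0.0563). The 10 most abundant genes together held 38.3 ± 3.11% and 41.5 ± 4.72% (exact permutation p = 0.195, n = 6 per group).

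Markers of hepatocytes had a median log2 change of 0.00 over 15 genes (camera adjusted p = 0.483), and those of other liver cells leaned both ways without passing. The 18 Kupffer cell and macrophage markers had a median of 0.29 (adjusted p = 0.0506), the 12 stellate cell and fibroblast markers -0.28 with all 12 negative (adjusted p = 0.140), the 5 T and NK cell markers -0.57 (adjusted p = 0.229), the 5 monocyte markers -0.35 (adjusted p = 0.972), the 13 endothelial markers -0.15 (adjusted p = 0.571) and the 7 red blood cell markers -0.43 (adjusted p = 0.422). Alb, the plasma albumin gene, was at 17788 ± 5705 and 19951 ± 2544 TPM.

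The metabolic genes fixed in advance and reported here did not pass the test. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was at 16.8 ± 18.9 TPM in controls and 6.45 ± 2.17 TPM with selenium, with a 95% interval of the log2 change from -1.85 to 0.47. Control 2 held 52.9 TPM, and without it the log2 change went from -0.69 to -0.24. The fatty acid synthase gene Fasn had an interval of -0.57 to 0.33, the desaturase Scd1 -0.67 to 1.37 (log2 change 0.35, or -0.11 without control 4), and the gluconeogenic genes Pck1 and G6pc -1.08 to 0.41 and -1.29 to 0.49. Mt1, a metallothionein, was at 548 ± 196 and 638 ± 506 TPM, and its log2 change of -0.67 had the opposite sign to the difference of means, with 38.9 TPM in selenium 1, without which the log2 change was -0.06. Lists of fatty acid synthesis (median 0.12, adjusted p = 0.140), cholesterol synthesis (0.04, adjusted p = 0.276), bile acid synthesis and transport (0.02, adjusted p = 0.811) and the proteasome (0.05, adjusted p = 0.144) did not pass camera.

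The authors' deposited table held more calls, from the submitters' own test. In the authors' deposited table an adjusted p under 0.05 was given to 1231 genes, 713 higher and 518 lower in selenium. Among the genes tested here were 985 of these, 696 higher and 289 lower in the authors' deposited table. That balance is opposite to the 2 higher and 31 lower genes called here. Of all 1231, however, 317 also had at least a 2-fold change in the authors' deposited table. Of these 317, 47 were higher and 270 lower in selenium, which leans the same way as the calls here. In the authors' deposited table Hyou1 had a log2 change of 1.32 (adjusted p = 0.00253) and Derl3 1.77 (adjusted p = 1.39e-05). Of the 19 selenoproteins, 3 passed in the authors' deposited table, all higher, namely Txnrd1 (log2 change 0.55, adjusted p = 0.00418), Msrb1 (0.46, adjusted p = 0.0238) and Selenos (0.36, adjusted p = 0.00673). Of the 985 genes of the authors' deposited table, 98.1% had the same sign here, and 32 of the 33 genes called here also passed there. Both tests used the same libraries, so this is no independent support.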

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

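The tests of other splits of the libraries were chosen after the results were seen. Within the groups of 6, 5 of 148 sets of values had 1 library separated from the rest by a gap above Dixon's critical value for its share of the group's range, where chance alone gives about 5% of sets.

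The lipogenic desaturase Scd1 was at 26.4 TPM in control 4, against 133 to 278 TPM in the other controls. In the same library the heat shock list mean was 0.42, against -0.43 to -0.16 in the other controls. The inducible chaperone Hspa1b was at 77.7 TPM in selenium 3, against 8.82 to 19.0 TPM in the other selenium libraries. The transcription factor gene Zbtb7b was at 15.2 TPM in control 6, against 9.82 to 11.5 TPM in the other controls. The immediate early list mean was 0.026 in control 1, against 0.25 to 0.31 in the other controls.

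Over 100 of the 462 ways to split the 12 libraries into groups of 6, the real one included, 2 called as many genes as the real split, which called 33. That share lies under 0.05, but the test was chosen after the results were seen, and the count moved widely with 1 library left out. It also cannot separate the treatment from another difference between the groups, such as time of sampling. The highest of the other splits called 56 genes and set controls 1, 2, 3 and 5 with selenium 3 and 4 against the rest. A second draw of 100 splits, the real one included, held no other split with as many genes, and its highest other split called 5. For gene lists chance cannot be excluded: 99 of the 100 splits called as many lists as the 5 of the real one, and the highest other split called 24.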

How the results depend on the processing

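The clock covariates, the GC correction, the checks of the major urinary protein share and the set of 8 libraries with low Dbp were chosen after the data were seen. Where no cause is named below, the cause was not tested. The 33 called genes (2 higher, 31 lower) became 1 without a filter (0 and 1), 20 with median-of-ratios scaling (2 and 18), 12 with quantile normalization (2 and 10), 191 with TPM rescaled without mitochondrial genes (6 and 185), 56 with robust empirical Bayes (4 and 52), 255 with array weights (114 and 141), 0 with exact permutation tests per gene (0 and 0), 14 with a 2-fold minimum (1 and 13) and 1842 at an unadjusted p under 0.05 (700 and 1142). Genes higher were also 1 with a pseudocount of 0.1 and 1 with a filter of 5 TPM. Without mitochondrial genes the rescaling raises control values more than selenium values by construction. The smallest adjusted p of the exact test was 0.133, with 163 genes at its smallest possible p. With the clock covariate 21 genes passed (2 and 19), 19 of them among the 33, and with the first 2 clock components 0 (0 and 0), the median SE of the 31 lower genes going from 0.15 to 0.18 and their median change from -0.86 to -0.81. With the GC correction 55 passed, 13 of them higher, and 26 of the 33 remained. In the 8 libraries with low Dbp 47 passed (34 and 13), 9 of them among the 33.

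Leaving out 1 library gave 7 to 171 genes, 0 to 56 higher and 7 to 115 lower, and all 33 remained in the 171 called without control 6. With array weights 31 of the 33 remained. The 5 gene lists became 16 without a filter, 8 with array weights, 9 with the clock covariate, 10 with 2 clock components, 9 in the 8 libraries with low Dbp, 6 to 10 with 1 library left out, and 0 with camera's estimated correlation, 0 with fry and 0 with exact permutation, the smallest adjusted p being 0.986, 0.0695 and 0.212.

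The replicate numbers do not pair the mice: correlations of same-numbered libraries ran from -0.14 to 0.11, and 1 control and 0 selenium libraries correlated best with their own number. A fit with a replicate block called 3 genes (0 higher, 3 lower), all 3 among the 33, and took the male-biased list past the threshold (adjusted p = 0.0331). The selenoprotein list, with a mean log2 change from -0.15 to 0.09, and the TPM shares of mitochondrial-encoded genes and of the 10 most abundant genes stayed on their side of the threshold under every alternative run for them. The share of major urinary protein genes was lost in 4 of 12 fits with 1 library left out and with TPM rescaled without mitochondrial genes (exact permutation p = 0.0563, n = 6 per group). No named gene past the threshold changed direction under these alternatives; of 1685 values of the 63 named genes, 140 lost and 25 gained a call, and 42, of genes below the threshold, changed sign. Depth is unknown, so its effect on genes with low values cannot be given. Genes at 1 TPM or more numbered 10212 ± 165 in controls and 9788 ± 458 with selenium (exact permutation p = 0.0628, n = 6 per group).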

Other observations

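The tests with the clock components, of mitochondrial rRNAs, of the genes other than major urinary protein genes and the GC correction itself were chosen after the results were seen, and the genes of the next paragraph were picked after their values were seen.

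Several transcripts with large differences lay just short of the threshold by limma. Neat1, the RNA scaffold of nuclear paraspeckles, was at 26.1 ± 19.4 TPM in controls and 5.66 ± 2.44 TPM with selenium (adjusted p = 0.0615, limma), and the small nucleolar RNA hosts Snhg1 and Snhg12 had log2 changes of -0.61 and -0.70. The cyclins Ccnl1 and Ccnl2, found in nuclear speckles, were at 9.55 ± 2.68 and 4.62 ± 1.38 TPM and at 18.3 ± 5.21 and 9.46 ± 1.56 TPM. Ldha, lactate dehydrogenase A, was at 273 ± 65.6 and 490 ± 115 TPM (adjusted p = 0.0762, limma), the stress gene Ddit4 at 7.60 ± 5.77 and 2.05 ± 0.876 TPM, and the protease inhibitor gene Mug2 at 10.5 ± 6.81 and 2.40 ± 0.836 TPM. The 17 measured antigen presentation genes all had negative log2 changes, with a median of -0.36 (camera adjusted p = 0.144).

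The 31 genes lower in selenium, several of which encode splicing regulators or nuclear RNAs, had a median log2 change of -0.86. It was -0.80 after each library was corrected for GC content (30 genes). These genes were picked for low p in the same libraries, so their median alone cannot decide on GC bias. A further 39 splicing regulator and nuclear RNA genes were listed after the pattern was seen and before their own values were looked at. The 37 measured ones, such as Srsf11, Ddx5 and Hnrnpdl, had a median of -0.37, with 32 negative (exact permutation p = 0.0130 for the list mean, n = 6 per group). Of the 37, 20 were negative at an unadjusted p under 0.05 in limma, and 0 passed the threshold over all genes. After the GC correction the median of the 37 was -0.33, with 30 negative. The difference of their mean went from -0.38 (SE 0.11) to -0.31 (SE 0.09). The 37 were not picked on their values, so these values argue against GC bias as the only cause in the 37. With the first 2 clock components as covariates 0 genes passed, the median SE of the 31 going from 0.15 to 0.18 and their median to -0.81, and the difference of the mean of the 37 went from -0.38 (SE 0.11) to -0.39 (SE 0.17), so time of sampling cannot be told apart from an effect of the treatment, since the second component differs between the groups. Less nuclear-retained RNA in the selenium libraries may also underlie the pattern, whether through RNA handling and capture or through the liver itself. The summed TPM of long intergenic noncoding RNAs went the same way, at 1630 ± 201 and 1233 ± 247 (exact permutation p = 0.0173, n = 6 per group), and the treatment stays open as a biological explanation that was not tested apart from these.

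Beside the lower mitochondrial mRNAs, the rRNAs mt-Rnr1 and mt-Rnr2 had a mean log2 change of 0.11. Whether rRNA was depleted or polyadenylated RNA selected is not given, so the rRNA values may depend on library preparation. They cannot decide whether mitochondrial RNA of all kinds was lower. The 9943 tested genes other than major urinary protein and mitochondrial-encoded genes had a median of -0.0264, against abundant major urinary protein transcripts as the cause, since these would lower all other genes alike. After the GC correction the median of the 13 mRNAs was -0.35, from -0.60 before, and GC bias cannot be told apart from an effect of the treatment, since the value lies between the bounds set for each and these mRNAs have a median GC content of 37.1% against 49.2% over all tested genes.

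The median of the 23 genes of endoplasmic reticulum stress, 0.52, was 0.54 after the GC correction. Their median GC content was 48.9%, against 49.2% over all tested genes, so the correction could hardly move their median. That typical GC content, more than the corrected value, goes against GC bias as the cause. The median log2 change was 0.49 with the first clock component and 0.29 with the first 2 as covariates, between the bounds set. Since the second component differs between the groups, time of sampling cannot be told apart from an effect of the treatment. A response of the liver to the selenium-enriched fungus is a candidate explanation, as a hypothesis found on the same data. The list's call rests on the preset correlation, and feeding before sampling, which the labels do not give, was not tested.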
